A study of Danio rerio with 12 samples.

How the data were processed

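RNA was measured in gata1-GFP-positive cells sorted from 12-somite zebrafish embryos, with 3 arrays in each of 4 groups: wild type, TIF1g morphants, cdc73 morphants and double morphants. Per the labels' protocols, total RNA of about 200K sorted cells per sample was extracted with TRIzol and amplified with a MessageAmp II kit, and Roche NimbleGen did the labelling, with Cy3. Amplification of this kind starts at the poly(A) tail, so the signal of a probe can depend on its distance from the transcript's end. Groups and replicate numbers were taken from the sample titles. The description of TIF1g replicate 3 repeats the number of replicate 2, and its title was followed.

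The deposited files hold 1 linear intensity per probe and array, 389307 probes per array, of which 4307 are random-sequence controls and the rest interrogate 37157 targets. Per the file headers and names, the authors deposited these intensities after background correction and quantile normalization in the manner of RMA, at probe level. Values of the same rank over the 12 arrays differed by at most 0.0743 on the log2 scale, and the mismatch column was 0 throughout. A table of the whole series held 4620000 values equal to those of the array files. Software versions and the genome build behind the probe design are not given in the sources used here, and no coordinates are given for that reason.

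Intensities were turned to log2 values and summarised per target by median polish over the 12 arrays (tolerance 0.01, at most 20 rounds), without control probes and without further normalization. Of the targets, 21894 had 12 probes and 1026 had under 4. The random probes were grouped into 358 pseudo-targets of 12, and the 95th percentile of their means over the arrays, log2 5.99, was set against target means; the mean of 24350 targets lay above it, and the median target mean was 6.70. Within a group each array had its own random-probe level, the same percentile on that array. These levels averaged 6.07 in wild type, 6.51 in TIF1g morphants (6.23 to 6.90), 5.85 in cdc73 morphants and 5.78 in double morphants. A target at or below its array's level on all arrays of a group has only a bound there. Its fold is given as at least the brighter group's mean over the dim group's mean of, per array, the higher of the array's level and the target's own value. No fold is given where that bound is under 1 or both groups are dim, and the departure from additive effects is bounded in the same way.

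Target identifiers were matched without versions to the reference gene table of assembly GRCz12tu, used for names only. Of 3055 targets with a RefSeq transcript identifier 2663 were named, with 2650 symbols, 13 of them on several targets, and 392 were not matched. Targets with Vega (11285), Ensembl (10153), ZV (6756) and TC (3779) identifiers were tested but are not named here, and 193 named targets carry clone-like symbols, which are not printed. Of the genes to be named whatever their result, spi1b, hbae3 and hbbe3 were measured under a name, and trim33, cdc73, gata1a, tal1, lmo2, alas2, slc4a1a, fli1a and kdrl are not analysed here by name.

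Differences between groups were tested per target with limma (lmFit and eBayes, two-sided, all 12 arrays in 1 fit of group means, prior degrees of freedom 3.55, prior SD 0.194). The 6 contrasts were each morphant group against wild type, double against each single morphant group, and the interaction, double minus TIF1g minus cdc73 plus wild type. P-values were adjusted by Benjamini-Hochberg over all targets of a contrast, and a target was called at an adjusted p under 0.05. Errors of log2 differences are limma's standard errors, written SE; errors of group means are SD over 3 arrays. Where a contrast compares groups by gene, fold is 2 to the power of the size of the log2 difference.

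Gene lists for erythroid genes, other cell types the sort could hold, signalling, stress and housekeeping were written before the data were examined, as were the tests, the naming rule and the alternatives, apart from those named as later choices. Of 28 such lists 14 had at least 3 measured genes, and these and the union of the erythroid lists were tested with limma's camera (preset correlation 0.01, 2650 genes, the brightest target per symbol), with adjustment over the 15 tested lists of a contrast. Correlations estimated from the data were run as an alternative. 8 further lists were chosen by symbol pattern after seeing the data, and tested also after removal of the reach and level trend. Calls are also given adjusted over the list alone. Named genes were the 10 largest rises and 10 largest falls per main contrast (5 for double against cdc73 and for the interaction) with an adjusted p under 0.05 and a usable symbol. These also had the 3 arrays of 1 group beyond the 3 of the other (not asked for the interaction) and a brighter group mean above the median of all targets. Up to 4 called members of each list with the largest changes were added. The rule gave 122 genes.

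Return toward wild type was measured on held-out arrays: targets were chosen without 1 TIF1g and 1 wild-type array, and the ratio of the double minus TIF1g change to the TIF1g minus wild-type change was taken on the arrays held out, over 9 pairs. Overlaps of calls were set against independent lists and against unchanged groups simulated on shared wild-type values (20 simulations). Trends with probe reach were removed, in 1 alternative, by a smooth (mgcv) of each array's deviations on level and reach.

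The steps were tested on simulated data for the TIF1g against wild-type comparison with 37157 targets: of 50 targets changed at each size, 4 were recovered at a log2 change of 0.5, 33 at 1, 47 at 2 and 49 at 3, and 4.32% of calls were false. For that comparison camera called 2% of 50 unshifted random lists of 17 genes and 100% of lists shifted by 0.5. The simulated values were independent between genes and had no array-wide trends. These rates therefore do not cover correlated genes or arrays that differ in background or in the trend with probe reach. Tools were R 4.3.3, limma 3.58.1, mgcv 1.9.3 and version 1.17.8 of data.table.

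Alternatives covered the summary of probes, further normalization, filters on dim targets, limma's variance model, array weights, the test, stricter thresholds, the replicate number as a block, leaving out each array and list definitions. Array background as a covariate, cyclic loess, removal of the reach and level trend, the probes nearest either end of a target, list matching through synonyms and the number of saturated probes as a block were chosen after seeing the data. No array was left out of the fits given first.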

Results

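RNA abundance was measured in zebrafish erythroid progenitors, the GFP-positive cells sorted from embryos that carry a gata1-GFP reporter, at the 12-somite stage. A sample held about 200K sorted cells. The 12 samples formed 4 groups of 3: uninjected wild type, embryos injected with a morpholino (an antisense oligomer that blocks translation or splicing of a transcript) against TIF1g, embryos injected with a morpholino against cdc73, and embryos injected with both, called double morphants here. Each morpholino is labelled 100 nM. No group got a control morpholino, wild type got none, and double morphants got both doses. Effects of injection and of total dose thus cannot be told apart from those of the targeted genes. TIF1g (also named trim33) is a nuclear regulator of transcription needed for blood formation in zebrafish, and cdc73 encodes a subunit of the PAF1 complex, which acts on elongating RNA polymerase II. Every sample was hybridised to its own single-colour oligonucleotide array with probes for 37157 targets, and the values below are log2 target intensities. The number of arrays limits the precision of every value. Between 58.5% and 69.9% of targets lay above the random-probe level on 11 arrays, and 50.1% did so on the remaining array, TIF1g replicate 3.

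The 95th percentile of the random-sequence probes, a measure of array background, was 391, 312 and 632 on the TIF1g arrays against 249, 168.5 and 295 on the wild-type arrays. It lay between 149 and 154 on the cdc73 arrays and between 114 and 183 on the double-morphant arrays. Replicates correlated across targets at 0.987 to 0.990 in wild type, 0.972 to 0.989 in TIF1g morphants, 0.994 to 0.995 in cdc73 morphants and 0.990 to 0.996 in double morphants. Gene names could be given to 2663 targets, 7.17% of all, and every statement on a gene or gene list concerns these. Neither trim33 nor cdc73 is among the named targets, so the knockdown of the targeted genes was not checked here. The labels do not say that replicates came from separate pools of embryos, so p-values measure only the spread between these samples, which may be technical.

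TIF1g morphants were compared with wild type to see what loss of TIF1g does to erythroid progenitors. All 4 measured globin genes fell, each lower on all 3 TIF1g arrays than on all 3 wild-type arrays. The embryonic alpha globin hbae4 fell 2.92-fold (log2 difference -1.54 ± 0.10 SE, n = 3 arrays per group), and the embryonic beta globin hbbe3 fell 1.56-fold (log2 -0.64 ± 0.10). A second embryonic alpha globin, hbae3, among the brightest targets at 14.77 ± 0.08 (SD) in wild type, changed by log2 -0.34 ± 0.09 (limma adjusted p = 0.0254). The adult alpha globin hbaa2 (log2 -0.83 ± 0.11) was above the random-probe level of each array in wild type (mean 6.51) but not in TIF1g morphants, whose arrays had a mean level of 6.51 themselves, so no bound on its fold is given. Among haem and iron genes, tmem14ca, needed for porphyrin transport into mitochondria, fell 2.45-fold (log2 -1.29 ± 0.13) and the haem synthesis enzyme ppox, above background on 2 of 3 TIF1g arrays, fell 2.11-fold (log2 -1.08 ± 0.17), while the mitochondrial glycine importer slc25a38a rose 1.92-fold (log2 0.94 ± 0.13).

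The globins were called lower as a list (median -0.74, or -0.49 with hbaa2 set at its bound; camera adjusted p = 0.000495), and all 4 members passed also when adjusted over the list alone. The call did not hold with an estimated correlation between genes (adjusted p = 0.287 with an estimated correlation) or over targets above the median level alone. Of 5 haem and iron genes 3 fell, 1 rose and 1 was not called, and 4 passed when adjusted over the list alone (camera adjusted p = 0.350). Of 6 erythroid and progenitor regulators 1 rose, the homeobox gene cdx1a (log2 0.74 ± 0.14), and 5 were not called (camera adjusted p = 0.371). The union of the erythroid lists was not called: 3 of its 17 genes rose, 7 fell and 7 were not called, against 11 that passed when adjusted over the list alone (median -0.03, mean -0.18, camera adjusted p = 0.350). The call of hbae3 was lost in 13 of 31 alternative settings and that of slc25a37 (log2 -0.51 ± 0.16), the third fall among haem and iron genes, in 18 of 31, with single arrays left out among them for both. With array background as a covariate, the calls of hbae3, cdx1a and spi1b were lost, while those of hbae4, hbbe3, tmem14ca, ppox and slc25a38a were kept. The probes nearest the target's start gave no call for ppox, hbaa2 and hbae3.

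Outside the erythroid lists, the largest rises in TIF1g morphants were in c2cd4a, 12.1-fold (log2 3.60 ± 0.17, from 6.47 ± 0.28 SD to 10.08 ± 0.20), in f3b, a tissue factor gene that starts blood coagulation, 7.16-fold (log2 2.84 ± 0.12), and in the matrix Gla protein gene mgp (log2 2.65 ± 0.20). The pro-apoptotic p53 target pmaip1 rose 5.71-fold (log2 2.51 ± 0.17). Of 22 listed p53 targets only pmaip1 and sesn2 were measured, and sesn2 was not called (log2 0.33). The muscle genes myl13 and acta1b (log2 2.08 ± 0.16 and 1.59 ± 0.14), seraf (1.97 ± 0.13), pde6hb (1.76 ± 0.20), sgk2b (1.66 ± 0.23) and ngfb (1.81 ± 0.35) also rose, with the call of ngfb lost when array background was a covariate and that of sgk2b lost with the probes nearest its start. Ordered by fitted values, the largest falls were in cyp46a1.2, a cytochrome P450 of the cholesterol hydroxylase family, at least 2.71-fold, sdr16c5b (log2 -2.40 ± 0.27), the histone H3 gene h3c13a, at least 2.42-fold, and fbxo36b (log2 -1.90 ± 0.20). As cyp46a1.2, h3c13a and stx2a were at background in TIF1g morphants, their place in this order is uncertain. Further falls were seen in cbr4 (-1.84 ± 0.22), igfbp5a, which binds insulin-like growth factors (-1.75 ± 0.17), stx2a, at least 2.06-fold, parvg (-1.63 ± 0.18), mettl27 (-1.62 ± 0.19) and the glycosyltransferase b3gnt3.1 (-1.56 ± 0.15). Of these, sdr16c5b, fbxo36b, cbr4, igfbp5a and parvg were above background on 2 of 3 TIF1g arrays, and parvg was at -0.53 and not called with the probes nearest its start.

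Markers of other cell types were not called as lists in TIF1g morphants. Of 7 muscle and somite genes 2 rose, 1 fell (mylpfb, log2 -1.13; -0.64 and no call with array background as a covariate) and 4 were not called (camera adjusted p = 0.371); of 5 myeloid genes 1 fell, the transcription factor spi1b (log2 -0.45 ± 0.10), and 4 were not called (camera adjusted p = 0.815). None of 5 endothelial genes was called by limma (camera adjusted p = 0.965). Of 3 pronephros genes 1 fell, osr1 (log2 -0.99), and camera pointed down (adjusted p = 0.892) although the median was 0.46 and the mean 0.02. Of 6 TGF-beta and BMP signalling genes, a pathway TIF1g acts on, 2 rose (bmpr1ba 0.92 and tgfb3 0.56), 1 fell (tgfb1a, log2 -0.72) and 3 were not called (camera adjusted p = 0.350). The call of tgfb3 was lost in 14 of 31 settings, leaving out each of 5 single arrays among them, and that of tgfb1a with array background as a covariate; bmpr1ba was above background on 1 of 3 wild-type arrays. The remaining lists, Notch signalling, heat shock and unfolded protein response, Hox and Cdx genes, ribosomal proteins, oxidative phosphorylation and transcription elongation factors, had 5 called genes among them and camera adjusted p between 0.350 and 0.965. The elongation list had a median of -0.03, a mean of 0.02 and a camera direction of down.

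Over all targets, limma called 2904 higher and 4985 lower in TIF1g morphants, 7889 in all or 21.2%, of which 275 and 320 were named targets. The number was 4499 without wild-type replicate 2, 5113 without TIF1g replicate 3 and 12577 without TIF1g replicate 2. It was 2607 with array background as a covariate, of which 51.1% were higher, and 65 with an unequal-variance test per target. Higher calls made up 36.8% of the total and 24.3% when array medians were centred, a scaling that moved the median of all targets to -0.10.

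**Figure D1:**
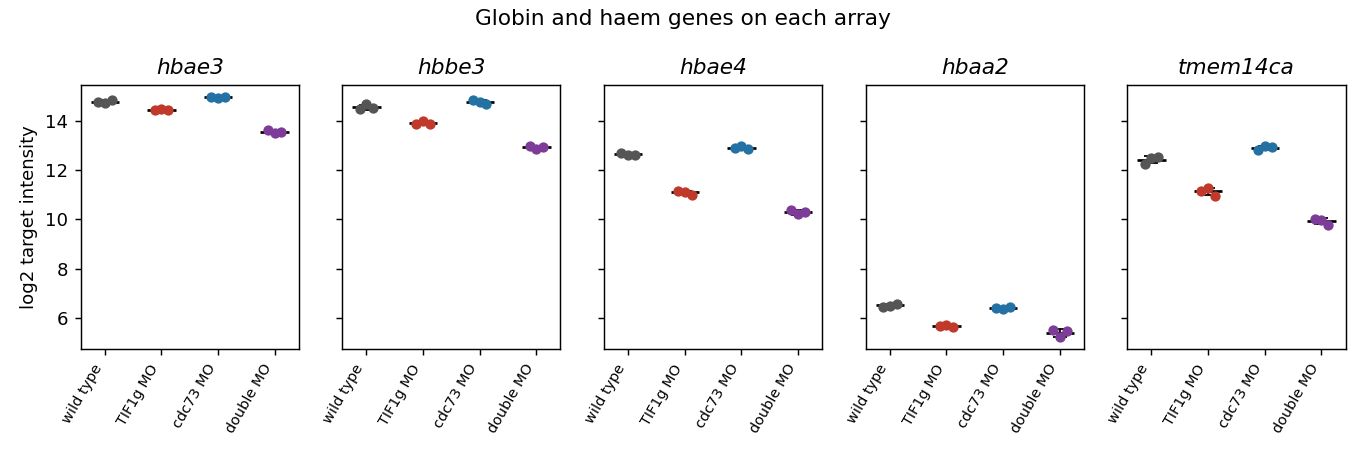
Log2 target intensity (vertical axis) of the globins hbae3, hbbe3, hbae4 and hbaa2 and of tmem14ca on each of the 3 arrays per group (points), with the group mean (wide bar) and SD (error bars), in wild type, TIF1g, cdc73 and double morphants. Values of hbae4 averaged 12.63 in wild type, 11.09 in TIF1g morphants, 12.90 in cdc73 morphants and 10.29 in double morphants, while group means of hbaa2 lay between 5.41 and 6.51, near the random-probe levels of the arrays, which averaged 5.78 to 6.51 in the groups.

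cdc73 morphants were compared with wild type to see what a lower dose of this elongation factor does alone. No globin gene was called: hbbe3 differed by log2 0.22 ± 0.10 (limma adjusted p = 0.141) and hbae3 by 0.17 ± 0.09 (limma adjusted p = 0.212, n = 3 arrays per group). The Polycomb gene cbx7a fell 13.1-fold (log2 -3.71 ± 0.10), from 12.38 ± 0.03 (SD) to 8.67 ± 0.04. Among the falls were 3 chaperone genes, the inducible hsp70.3 6.99-fold lower (log2 -2.80 ± 0.13), the Hsp110 family gene hspa4a 6.02-fold lower (log2 -2.59 ± 0.30) and the co-chaperone dnajb2 at least 6.37-fold lower. A list of 20 chaperone and co-chaperone genes formed after the data were seen had 11 lower and 3 higher and was not called (camera adjusted p = 0.149; adjusted p = 0.676 with an estimated correlation). Largest among the rises was ptk7a, which encodes a Wnt co-receptor of planar cell polarity, 8.88-fold (log2 3.15 ± 0.17).

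Among erythroid and progenitor regulators, pbx4 fell 2.72-fold (log2 -1.44 ± 0.11), the stem cell factor runx1 1.93-fold (log2 -0.95 ± 0.25) and hhex 1.35-fold (log2 -0.44 ± 0.12), with 3 further members not called (camera adjusted p = 0.580). Of 5 haem and iron genes tmem14ca rose (log2 0.48 ± 0.13), slc25a38a fell (log2 -0.54 ± 0.13) and 3 were not called (camera adjusted p = 0.864). The globins were not called as a list (median 0.19, camera adjusted p = 0.580). In the erythroid union 2 of 17 genes rose, 5 fell and 10 were not called, 8 passed when adjusted over the list alone, and camera pointed up (adjusted p = 0.940) while the median was -0.10 and the mean -0.12. The calls of runx1 and tmem14ca were lost with array background as a covariate and without wild-type replicate 1, and that of runx1 also without cdc73 replicate 2. The call of hhex was lost without wild-type replicate 1 or 2 or cdc73 replicate 3, and that of slc25a38a with the probes nearest its start (log2 -0.07) and after removal of the trend with probe reach and level.

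Both measured cell cycle genes, of 43 listed, fell in cdc73 morphants. The cyclin gene ccna2 fell 3.02-fold (log2 -1.60 ± 0.11) and the replication helicase gene mcm5 1.92-fold (log2 -0.94). Against wild type, 1 of these 2 genes was also called lower in TIF1g morphants (log2 -0.87) and both in double morphants (log2 -0.59 and -0.45). All 3 measured elongation genes were called: supt16h, a subunit of the histone chaperone FACT, fell 2.82-fold (log2 -1.49 ± 0.15), ube2a fell (log2 -0.44; lost in 12 of 30 settings) and ube2b rose (log2 0.65), with a camera adjusted p of 0.940. Of 4 heat shock and unfolded protein response genes 3 fell, 1 rose and all 4 passed when adjusted over the list alone (median -0.70, camera adjusted p = 0.580). Of 3 Notch signalling genes 2 fell (camera adjusted p = 0.580), and of 9 oxidative phosphorylation genes 4 rose and 2 fell (camera adjusted p = 0.580). Markers of other cell types included falls of spi1b (log2 -0.79 ± 0.10), the endothelial gene egfl7 (log2 -0.93) and the somite gene meox1 (log2 -1.16). There were also rises: 1 of 7 muscle and somite genes rose, and of 2 neural genes 1 rose (log2 0.89) and 1 fell (log2 -0.44). None of the myeloid, endothelial, muscle and pronephros lists was called, with camera adjusted p between 0.940 and 0.943, and for muscle and pronephros camera pointed up while median and mean were below 0. TGF-beta and BMP signalling and the ribosomal proteins had 2 called genes each and Hox and Cdx genes 1, none called as a list (each camera adjusted p = 0.940); for the first 2 of these, camera again pointed up with a negative median.

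Further rises in cdc73 morphants were those of il12a (log2 2.35 ± 0.35), the selenoprotein genes selenow2b (2.29 ± 0.20) and selenou1b (at least 2.65-fold), the caveolin gene cav4b (2.2 ± 0.13), the ionocyte transcription factor gene foxi3a (2.05 ± 0.15), neurl1aa (2.03 ± 0.16), rgn (1.94 ± 0.32), the nucleoside kinase gene uck1 (1.92 ± 0.11) and fut9b.1 (1.78 ± 0.22). Of these, cav4b, neurl1aa and rgn were above background on 1 of 3 wild-type arrays. The rise of neurl1aa was absent from the probes nearest the start of its target (log2 -0.05). Further falls were those of the fucosyltransferase gene fut10 (log2 -3.17 ± 0.15), tent5ba (-2.55 ± 0.13), napbb (at least 4.25-fold), lims1 (-2.18 ± 0.17), ppp1r14ba (-2.16 ± 0.11) and the isoprenoid synthesis gene idi1 (-2.13 ± 0.13), for which the probes nearest the target's end gave -0.26 and no call. The p53 target pmaip1 rose 3.32-fold (log2 1.73 ± 0.17), while the only other measured p53 target, sesn2, fell (log2 -0.60).

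In total 5590 targets were called higher and 5997 lower by limma in cdc73 morphants, 31.2% of all, and 271 and 597 of these were named. All 3 wild-type arrays had many probes tied at the array maximum (59 to 71) and all 3 cdc73 arrays few (7 to 19), so no value within a class can be given. With this class as a block, estimated from the other groups, 6881 targets were called, and none was called for the class itself. The calls lost included those of runx1, hhex, tmem14ca, ube2a and ube2b. Over all contrasts this block lost 48 of 288 called results of named genes. The difference from wild type varied with how far a target's last probe lay from the start of its sequence. Among 6558 bright targets the rank correlation across targets, which are not independent replicates, was -0.21, and the median difference went from 0.06 for targets reaching up to 500 bases to -0.25 for those reaching over 2000 bases. The same rank correlation was 0.11 for TIF1g morphants and 0.20 for double morphants against wild type, and 0.15 for double against TIF1g morphants.

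**Figure D2:**
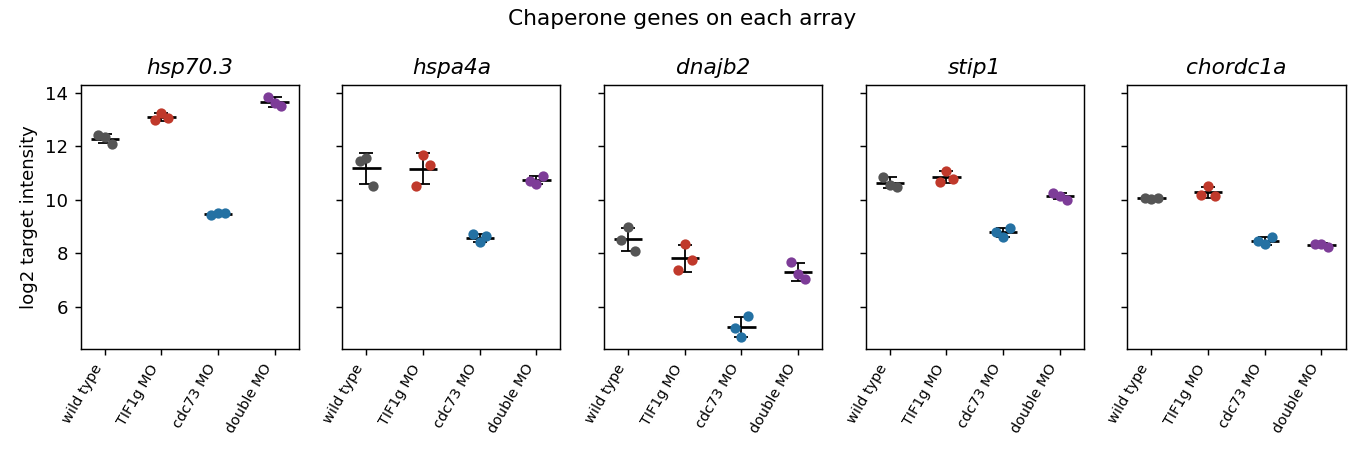
Log2 target intensity (vertical axis) of 5 chaperone and co-chaperone genes on each of the 3 arrays per group (points), with group mean (wide bar) and SD (error bars), in the 4 groups. The cdc73 arrays lie below the wild-type arrays for each gene, with hsp70.3 at 9.47 against 12.28 and at 13.65 in double morphants. The genes come from a list of 20 formed after the data were seen. In cdc73 morphants 11 of these 20 fell, 3 rose and 6 were not called. For the plot stip1 was picked after its values were seen, and the others were named for large changes. The plot is therefore no evidence on the list.

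Double morphants were compared with wild type to see which changes remained when both genes were lowered. All 4 globins fell again, each lower on all 3 double-morphant arrays than on all 3 wild-type arrays. The falls were 5.06-fold for hbae4 (log2 -2.34 ± 0.10, n = 3 arrays per group), 3.09-fold for hbbe3 (log2 -1.63 ± 0.10), 2.34-fold for hbae3 (log2 -1.22 ± 0.09) and at least 1.66-fold for hbaa2. The porphyrin transport gene tmem14ca fell 5.62-fold (log2 -2.49 ± 0.13) and ppox 2.19-fold (log2 -1.13 ± 0.17), and no haem or iron gene rose. The hormone gene fgf21 fell (log2 -3.40 ± 0.23) to a level close to background, 5.96 ± 0.43 (SD), above the array's random-probe level on 2 of 3 double-morphant arrays, so the size of its fall is uncertain in every comparison with double morphants.

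The globins were called as a list (median -1.42, also with hbaa2 at its bound; camera adjusted p = 1.19e-05; adjusted p = 0.0622 with an estimated correlation). The erythroid union, which includes these 4 globins, was also called lower. Of its 17 genes 8 fell, 1 rose and 8 were not called, and 10 passed when adjusted over the list alone. Its median was -0.53 (camera adjusted p = 0.00142, or adjusted p = 0.0622 with an estimated correlation). Measured were 4 of 15 listed globins, 5 of 29 haem and iron genes, 2 of 22 erythroid structure and enzyme genes and 6 of 35 regulators. Of 5 haem and iron genes 2 fell and 3 were not called (camera adjusted p = 0.20), and of 6 regulators 1 fell, hhex (log2 -0.57; no call with the median of probes, from the probes nearest its end or after removal of the trend with probe reach and level), and 5 were not called (camera adjusted p = 0.496). Other cell types were not called as lists: 2 of 7 muscle genes fell (median -0.40, camera adjusted p = 0.20), 1 of 5 myeloid genes fell, spi1b (log2 -0.36, lost in 12 of 31 settings, without wild-type replicate 2 or 3 or double replicate 1 or 2 among them; camera adjusted p = 0.771), 1 of 5 endothelial genes rose, the apelin receptor gene aplnrb (log2 1.16; camera adjusted p = 0.219), and none of 3 pronephros genes was called by limma (camera adjusted p = 0.943, pointing up, with a median of -0.04). Of 3 Notch signalling genes 2 rose, rbpja (log2 0.70) and her12 (0.88), and camera gave an adjusted p of 0.0569. The TGF-beta and BMP genes tgfb3 (1.24), bmpr1ba (0.81) and bambib (0.47) rose among 6 measured (camera adjusted p = 0.20). Of 5 ribosomal protein genes 2 fell, rpl37 (log2 -1.41) and rpl27a (log2 -0.66), and of 9 oxidative phosphorylation genes 2 fell, ndufa11 (log2 -1.24) and cox5b2 (log2 -0.86), with camera adjusted p of 0.20 and 0.219. Heat shock and unfolded protein response genes, elongation factors and Hox and Cdx genes were not called as lists (camera adjusted p 0.20, 0.778 and 0.548).

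The largest rises in double morphants were in pglyrp6, a peptidoglycan recognition protein gene (log2 2.62 ± 0.13, 6.15-fold), c2cd4a (2.2 ± 0.17), tmbim1a (2.05 ± 0.16), the lens gene lim2.3 (1.93 ± 0.13), pmaip1 (1.92 ± 0.17), mgp (1.84 ± 0.20), ywhae2 (1.65 ± 0.12) and the RNA-binding protein gene msi1a (1.58 ± 0.15). At least 2.78-fold and 1.73-fold rises were measured for vstm2a and the connexin gene gjb9a. Outside the erythroid lists, the largest falls after fgf21 were in idi1 (log2 -2.46 ± 0.13; -0.31 and no call from the probes nearest its end), lrrc10 (-2.44 ± 0.15), rab33a (-2.22 ± 0.13), b3gnt3.1 (-2.22 ± 0.15), jmjd7 (-2.12 ± 0.12), the aquaporin gene aqp8a.2 (-2.03 ± 0.14) and the deoxycytidine kinase gene dck (-1.99 ± 0.14). The call of mgp was lost with the probes nearest its start. Besides pmaip1, the only other measured p53 target, sesn2, was called higher (log2 0.53). In all, limma called 4953 targets higher and 4805 lower, 26.3%, of which 280 and 405 were named.

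Targets called in a single-morpholino group and in double morphants coincided more often than independent lists would. Of targets higher in TIF1g morphants 1036 were also higher in double morphants, against 387 for independent lists, and 2230 were lower in both, against 645. For cdc73 and double morphants these numbers were 2161 against 745 higher and 2013 against 776 lower. Between the 2 single-morpholino groups they were 592 against 437 and 1439 against 805. Opposite calls between these 2 groups were as numerous as for independent lists among targets higher in TIF1g morphants (468 against 469) and more numerous among those lower in TIF1g morphants and higher in cdc73 morphants (1121 against 750). All 3 comparisons share the wild-type arrays, and unchanged groups simulated against them gave a correlation of 0.50 between log2 differences. The observed correlations were 0.30 for TIF1g with double, 0.41 for cdc73 with double and -0.08 for TIF1g with cdc73, and the covariances differed from the simulated ones by 0.0705, 0.125 and -0.0502. With 3 wild-type arrays the controls could not be split into parts of at least 2, and part of the excess overlap may come from the shared controls. The numbers for independent lists also take all 37157 targets as equally likely to be called, while 24350 had a mean above the random-probe level. Unequal chances of a call may add to the excess.

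Double morphants were compared with TIF1g morphants to see whether lowering cdc73 restores erythroid genes in TIF1g deficiency. Of the 4 globins lower in TIF1g morphants 3 were lower still in double morphants: hbbe3 fell 1.97-fold (log2 -0.98 ± 0.10, n = 3 arrays per group), hbae3 1.85-fold (log2 -0.89 ± 0.09) and hbae4 1.74-fold (log2 -0.79 ± 0.10), each on all 3 double-morphant arrays below all 3 TIF1g arrays. The remaining globin, hbaa2, was at background in both groups and was not called. The haem gene tmem14ca fell 2.30-fold (log2 -1.20 ± 0.13). Tissue factor f3b, raised in TIF1g morphants, fell 16.7-fold (log2 -4.06 ± 0.12) to 8.12 ± 0.13 (SD), below its wild-type level of 9.34 ± 0.14. The myeloid factor spi1b did not differ detectably (log2 0.09 ± 0.10, limma adjusted p = 0.517).

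The globins were called lower as a list (median -0.84, also with hbaa2 at its bound, as hbaa2 was at background in both groups; camera adjusted p = 0.0135; adjusted p = 0.296 with an estimated correlation). In the erythroid union 9 of 17 genes fell, none rose and 8 were not called, 10 passed when adjusted over the list alone, and the median was -0.39 (camera adjusted p = 0.0135; adjusted p = 0.174 with an estimated correlation). Both calls were also lost with the median of probes, with the probes nearest the start and without TIF1g replicate 2, where the erythroid median was -0.44 (adjusted p = 0.0528 in limma's camera). Of 6 regulators 3 fell, cdx1a (log2 -1.05), runx1 (log2 -1.04 ± 0.25) and hhex (log2 -0.53), with camera adjusted p = 0.220. Of 5 haem and iron genes slc25a38a (log2 -0.75) fell besides tmem14ca (median -0.05, mean -0.35, camera adjusted p = 0.515). The calls of cdx1a, runx1 and slc25a38a were lost with array background as a covariate, where runx1 was at log2 0.03. Of 7 muscle and somite genes 3 fell, acta1b most (log2 -1.75), and 1 rose (camera adjusted p = 0.149). Of 5 endothelial genes 2 rose and 1 fell (camera adjusted p = 0.254), and 1 of 5 myeloid genes fell, the cytokine gene il1b, which was at background in both groups (camera adjusted p = 0.585). Of 3 pronephros genes 1 rose and 1 fell, with a negative median and an upward camera direction (adjusted p = 0.698). TGF-beta and BMP signalling had 2 genes higher and 2 lower (median 0.08, mean -0.10, camera adjusted p = 0.585), and Notch signalling 2 higher and 1 lower (camera adjusted p = 0.254). The other lists, with 1 gene higher and 7 lower among 24, had camera adjusted p between 0.220 and 0.846.

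Rises from TIF1g to double morphants were largest for tmbim1a (log2 2.51 ± 0.16, 5.70-fold), lim2.3 (1.90 ± 0.13), pglyrp6 (1.89 ± 0.13), the alcohol dehydrogenase gene adh8a (1.67 ± 0.16) and the hedgehog ligand gene ihha (1.57 ± 0.13). The calls of wdr54 (1.75 ± 0.20), scp2b (1.64 ± 0.26), mettl8 (1.59 ± 0.17) and cyp46a1.2 (at least 1.47-fold) were lost with array background as a covariate. The collagen-modifying enzyme gene plod2 rose on 1 of its targets (1.51 ± 0.15; above background on 1 of 3 TIF1g arrays) and not on the other (log2 -0.26). Falls after f3b were largest for fgf21 (log2 -2.92 ± 0.23), idi1 (-2.58 ± 0.13; -0.13 and no call from the probes nearest its end), lrrc10 (-2.57 ± 0.15), cbx7a (-2.44 ± 0.10), rab33a (-2.12 ± 0.13), the transcription factor gene egr3 (-2.06 ± 0.14), emp3b (-1.98 ± 0.11), the chaperone gene chordc1a (-1.96 ± 0.12) and seraf (-1.81 ± 0.13).

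For the whole set of targets changed in TIF1g morphants, the return toward wild type was measured on arrays not used to choose the targets, over 9 pairs of a held-out TIF1g and a held-out wild-type array. Targets lower in TIF1g morphants differed from wild type by a median of -0.95 on the held-out arrays and went up by 0.41 from TIF1g to double morphants, a median ratio of -0.475 (from -0.652 to -0.292), where -1 would be a full return. They remained at -0.46 against wild type in double morphants and were at -0.05 in cdc73 morphants. Targets higher in TIF1g morphants had a median ratio of -0.364 (from -0.820 to 3.14, the last from a pair whose held-out difference was near 0). In that pair, with TIF1g replicate 2 and wild-type replicate 1 held out, the 6708 chosen targets differed by a median of -0.05. The changes chosen on TIF1g replicates 1 and 3 were weaker on replicate 2. Lowered targets differed there by -0.27, -0.60 and -0.38, against -1.37 to -0.77 in the other pairs. The globins hbae3, hbae4 and hbbe3 and tmem14ca, also lower in TIF1g morphants, moved further from wild type in the same comparison. The held-out TIF1g array enters both parts of the ratio, which pushes array-wide differences such as background toward -1.

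A total of 7041 targets were higher and 6389 lower in double than in TIF1g morphants by limma, 36.1%, of which 355 and 569 were named. Higher calls made up 52.4% of the total and 60.7% when array medians were centred. The total was 8461 without double-morphant replicate 1 and 2128 with array background as a covariate, of which 37.8% were higher.

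Double morphants were compared with cdc73 morphants to see what loss of TIF1g adds when cdc73 is low. All 4 globins fell: hbae4 6.07-fold (log2 -2.60 ± 0.10, n = 3 arrays per group), hbbe3 3.58-fold (log2 -1.84 ± 0.10), hbae3 2.62-fold (log2 -1.39 ± 0.09) and hbaa2 at least 1.54-fold. The haem genes tmem14ca (log2 -2.97 ± 0.13) and ppox (log2 -0.88 ± 0.17) fell as well. The chaperone gene hsp70.3 rose 18.1-fold (log2 4.18 ± 0.13), tent5ba 9.09-fold (log2 3.18 ± 0.13) and cbx7a 5.89-fold (log2 2.56 ± 0.10), all of them genes that fell in cdc73 morphants. The phosphodiesterase gene pde6hb (2.42 ± 0.20) and the ribosome export gene nmd3 (2.41 ± 0.13) rose, and fgf21 (log2 -3.86 ± 0.23), selenow2b (-3.32 ± 0.20), ptk7a (-3.28 ± 0.17) and emp3b (-3.01 ± 0.11) fell.

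The globins were called as a list (median -1.62, also with hbaa2 at its bound; camera adjusted p = 9.19e-06; adjusted p = 0.0784 with an estimated correlation), as was the erythroid union (2 of 17 higher, 8 lower, 7 not called, 10 when adjusted over the list alone; median -0.25; camera adjusted p = 0.00527; adjusted p = 0.0784 with an estimated correlation). Of 9 oxidative phosphorylation genes 6 fell, cox5b2 most (log2 -1.63 ± 0.14), and 1 rose (median -0.64, camera adjusted p = 0.00986; adjusted p = 0.230 with an estimated correlation). All 3 Notch signalling genes rose, rbpja (1.23), her12 (1.12) and mib1 (1.12), with camera adjusted p = 0.0301 and adjusted p = 0.140 with an estimated correlation. The list calls of oxidative phosphorylation and Notch signalling were lost in 5 and 8 of 35 settings. Of 4 heat shock and unfolded protein response genes, hspa4a, ddit3, sesn2 and trib3, 3 rose (camera adjusted p = 0.0565). Of 5 haem and iron genes 3 fell and 1 rose (camera adjusted p = 0.0700). The call of the third, slc25a37 (log2 -0.47), and that of epor were lost when single arrays were left out. Among other cell types 3 of 5 endothelial genes rose (camera adjusted p = 0.162), and the myeloid, muscle and pronephros lists had camera adjusted p of 0.933, 0.309 and 0.952. Regulators, with pbx4 higher (1.49) and epor lower (log2 -0.71), elongation factors, TGF-beta and BMP signalling, Hox and Cdx genes and ribosomal proteins, with rpl37 lower (log2 -1.83), had camera adjusted p between 0.240 and 0.933. In total, limma called 6441 targets higher and 5830 lower, 33.0%, of which 561 and 379 were named. The difference rose with the reach of a target's probes (rank correlation across 6558 bright targets 0.35).

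**Figure D3:**
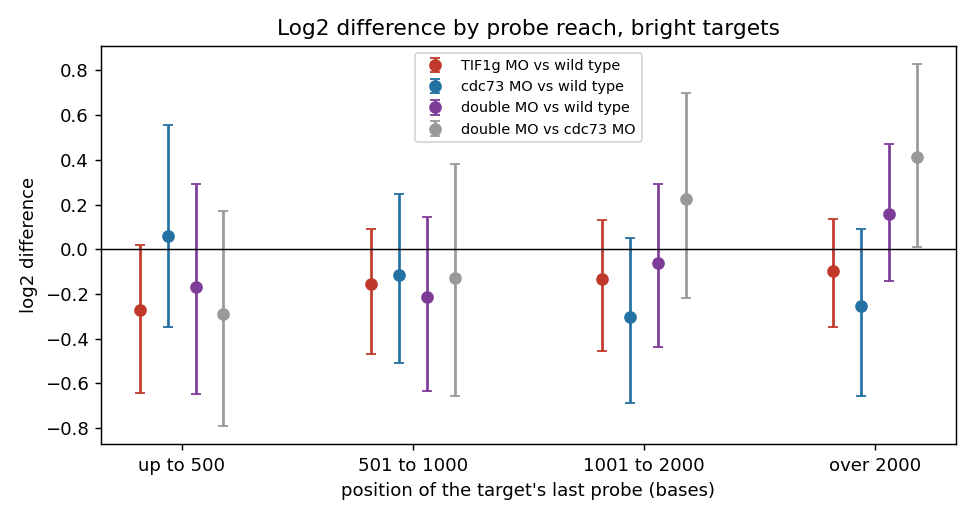
Log2 difference (vertical axis) of bright targets grouped by the position in bases of their last probe (horizontal axis), as median (point) and quartiles (error bars), in 4 comparisons. Medians went from 0.06 to -0.25 for cdc73 morphants against wild type and from -0.29 to 0.41 for double against cdc73 morphants, between targets reaching up to 500 bases and over 2000 bases.

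The departure of the double morphants from the sum of both single effects on the log2 scale was tested as an interaction. For 3 globins the double morphants lay below that sum: hbbe3 by log2 -1.20 ± 0.15 (limma adjusted p = 0.000174), hbae4 by -1.06 ± 0.14 and hbae3 by -1.05 ± 0.13. The same held for tmem14ca (log2 -1.68 ± 0.18), pmaip1 (log2 -2.32 ± 0.24), which rose in each of the 3 morphant groups, and acta1b (log2 -1.85 ± 0.20). Above the sum were hsp70.3 (3.37 ± 0.19), fut10 (2.93 ± 0.21), dnajb2 (at least 2.17, as it was at background in cdc73 morphants), tmbim1a (2.42 ± 0.23), nmd3 (2.39 ± 0.19), pbx4 (1.43 ± 0.15), ccna2 (1.34 ± 0.16), rbpja (1.31 ± 0.17) and spi1b (0.88 ± 0.14). The largest negative departures were those of f3b (log2 -3.70 ± 0.17), fgf21 (-3.38 ± 0.32, near background in double morphants), emp3b (-3.21 ± 0.16), ptk7a (-3.05 ± 0.24) and the small heat shock gene hspb7 (-2.86 ± 0.35).

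As lists, the globins (3 of 4 called, median -1.06, camera adjusted p = 0.00740; adjusted p = 0.298 with an estimated correlation) and the erythroid union (1 of 17 higher, 6 lower, 10 not called; median -0.21, camera adjusted p = 0.0265; adjusted p = 0.298 with an estimated correlation) departed downward. The call of the union was lost in 8 of 33 settings, and that of the globins also after removal of the trend with probe reach and level. Muscle, Notch signalling, heat shock and unfolded protein response, and oxidative phosphorylation each had a camera adjusted p of 0.163. The remaining lists lay between 0.210 and 0.913. Of all targets, limma called 5118 above and 3230 below the sum, 22.5%, of which 404 and 235 were named. The share above the sum was 61.3%, and 49.8% after cyclic loess. The departure rose with the reach of a target's probes (rank correlation across 6558 bright targets 0.31), with a median of 0.53 for targets reaching over 2000 bases.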

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

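The tests of a lower share of erythroid cells, of exchanged arrays and of splits after removal of additive effects were chosen only after the result was seen. For array background, counts under a background covariate had been seen before the test, and the list of chaperones was itself chosen after seeing the data.

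Several genes differed in their response to a morpholino depending on whether the other morpholino was also injected, by limma's interaction test. Among the globins the interaction had a median of -1.06 on the log2 scale, with hbbe3 at -1.20 and hbae3 at -1.05, and over the erythroid union the median was -0.21. Below the sum of both effects were also f3b (log2 -3.70), fgf21 (-3.38), emp3b (-3.21), ptk7a (-3.05) and hspb7 (-2.86). Above it were hsp70.3 (log2 3.37), fut10 (2.93), dnajb2 (2.76 as fitted and at least 2.17, as it was at background in cdc73 morphants), tmbim1a (2.42), nmd3 (2.39) and spi1b (0.88). In all, 73 of the 122 genes named here had an interaction past the threshold, against 22.5% of all targets. The naming rule picked large changes, the largest interactions among them, which raises the number among named genes. Of 100 splits of the 12 arrays, drawn with the real one included, 2 gave at least as many interaction calls as the real 8348, and the highest other gave 9672. Such splits also move the effect of each morpholino into the spread, so they do not test the interaction by itself. When the additive effect of each morpholino was first removed, 1 of 100 splits, the real one, gave as many calls, and the highest other gave 6179. The values left after this removal still hold any interaction, which goes into the spread of the other splits. The real split alone is also the smallest share that 100 splits can give. By this approximate test the count was above those of the other splits drawn, which does not exclude chance.

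The fall of the globins in double morphants was the first pattern weighed (median log2 -1.42, 4 genes). Removing the trend with probe reach and level left a median of -1.19 with all 4 genes called (from -2.0 to -0.91), and -0.67 with 3 called against TIF1g morphants, which argues against that trend as the whole cause. A lower share of erythroid cells in the sort would raise the markers of the cell types that took their place. The prediction written for it was that the list of every other cell type would rise, and not all did. List medians were -0.40 for muscle (mean -0.353 ± 0.0676 SE over 7 genes of the same arrays), -0.07 for myeloid, 0.20 for endothelial and -0.04 for pronephros genes. Only these lists had at least 3 measured genes, and the endothelial median lay above 0. A rise of a single or an unmeasured cell type could escape this test, so a lower share stays open. An exchange of the double and TIF1g arrays stays open: after an exchange the TIF1g and cdc73 differences should share the most covariance, and they shared -0.0502 beyond the simulated value, but effects that do not add up could give that too. A biological explanation, that lowering both genes at once lowers globin expression further than TIF1g loss alone, is a hypothesis that these arrays may fit but cannot establish.

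The lower chaperone genes in cdc73 morphants were the second pattern (20 genes, median log2 -0.61, 11 lower and 3 higher, not called as a list, with camera adjusted p = 0.149). Probes nearest the end of each target gave a median of -0.45 with 11 lower, and those nearest the start -0.66 with 12 lower, so probe position could account for part of the size but its share cannot be told apart from the effect. Removing the trend with reach and level gave -0.42 with 11 lower, which leaves that trend open in the same way. Lower chaperone expression after cdc73 loss stays open as the biological explanation and was not tested further.

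The third pattern was the number of targets called between TIF1g morphants and wild type, 7889, given that array background differed by 0.88 on the log2 scale between the groups. Within groups, targets differ in how they follow array background, and this slope correlated across targets at 0.605 with the TIF1g difference from wild type; 79.0% of called targets had the sign that the slope predicts. The random-sequence probes themselves, outside the main measurement, reached 391, 312 and 632 on TIF1g replicates 1, 2 and 3, above every wild-type array. Background could be a source of part of these calls: with it as a covariate, which also widens the errors because it differs between the groups, 2607 were called, 2248 of them among the 7889 and in the same direction. Double against TIF1g morphants gave -0.615 for the same correlation, and the interaction gave -0.344. It was -0.245 for cdc73 and -0.122 for double morphants against wild type, and 0.139 for double against cdc73 morphants. Background could likewise be a source of part of the calls between double and TIF1g morphants, 13430 without and 2128 with the covariate. Whether TIF1g loss itself altered the RNA in a way that changes background was not tested and stays open.

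The 6 arrays of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. In each comparison of target counts 1 of the 10 splits, the real one, gave as many calls. Every other split mixes the 2 groups, so any difference between these goes into the spread and lowers its count. Low counts in the other splits are therefore no separate evidence. The real count and the highest of the other splits were 7889 and 950 for TIF1g against wild type, 11587 and 0 for cdc73 against wild type, 9758 and 0 for double against wild type, 13430 and 1 for double against TIF1g, and 12271 and 0 for double against cdc73. For the erythroid median the real value and the highest other, by size, were -0.03 and 0.124 for TIF1g against wild type (8 of 10 splits as far from 0), -0.10 and 0.0870 for cdc73 (1 of 10), -0.53 and 0.308 for double against wild type (1 of 10) and -0.39 and 0.222 for double against TIF1g (1 of 10).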

How the results depend on the processing

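Array background as a covariate, probes nearest either end, trend removal, cyclic loess and saturated probes were tests chosen only after the result was seen. Each count of called targets was computed under 29 to 33 alternatives and each list under up to 36, and none of the 288 called results of named genes was called the other way: 275 kept their sign in every setting and 131 their call. For the changed results below the cause was not tested, except that stricter thresholds call fewer targets by construction. Targets called under a required log2 change of 1 numbered 2331 (TIF1g), 3962 (cdc73), 2856 (double), 3921 (double against TIF1g), 4393 (double against cdc73) and 4371 (interaction). At an adjusted p under 0.01 they numbered 3760 for TIF1g, 6323 for double, 7156 for double against TIF1g and 4742 for the interaction. An unequal-variance test per target called 65, 5517, 4198 and 1255 for TIF1g, cdc73, double and double against TIF1g. Array weights gave 16612 (TIF1g), 24221 (double against TIF1g) and 13977 (interaction), from a weight estimate that stopped before its tolerance was met. TIF1g replicate 1 got a weight of 22.2, against 0.247 and 0.339 for TIF1g replicates 2 and 3. For the TIF1g group these 3 counts thus rest largely on replicate 1. With array background as a covariate 2607 were called for TIF1g and 2128 for double against TIF1g. Only the 2 groups compared gave 2994, and the probes nearest the start 5158, for TIF1g. The block of saturated probes gave 6881 for cdc73 and 4808 for the interaction; arrays with many saturated probes alone, with 1 TIF1g array, gave 2774 (TIF1g) and 3490 (double against TIF1g), and those with few, with 1 double array, 2462 (double against TIF1g) and 4641 (double against cdc73). A lone array is assumed there to vary like the other groups, so these counts say nothing about stability. Numbers of settings in which a call was lost include these subsets where they hold the groups compared. Leaving out each array gave 4499 (without wild-type replicate 2) to 12577 (without TIF1g replicate 2) for TIF1g, 9413 to 12669 for cdc73, 7710 to 10837 for double, 8461 (without double replicate 1) to 16617 for double against TIF1g, 10205 to 13310 for double against cdc73 and 6736 to 10432 for the interaction; TIF1g replicate 3 left out gave 5113. The erythroid union lost its call in double against TIF1g morphants with the median of probes (-0.44, adjusted p = 0.0849), at an adjusted p under 0.01 (-0.39), with an estimated correlation (-0.39, adjusted p = 0.174), with the probes nearest the start (-0.59, adjusted p = 0.112) and without TIF1g replicate 2 (-0.44, adjusted p = 0.0528), all by limma's camera. In arrays with few saturated probes, 1 double against 2 TIF1g arrays, its median was -0.39 (camera adjusted p = 0.178), which decides nothing. In double morphants it was lost with an estimated correlation (-0.53, camera adjusted p = 0.0622). In TIF1g morphants it became called by limma's fry (-0.031, adjusted p = 0.000250), which does not compare it with other genes, and by camera without the regulators (-0.51, adjusted p = 0.00817). In cdc73 morphants fry pointed down (-0.10, adjusted p = 0.00842) and camera up. Leaving out arrays gave erythroid medians of -0.14 to -0.03 (TIF1g), -0.11 to 0.01 (cdc73), -0.54 to -0.47 (double) and -0.44 to -0.33 (double against TIF1g). The replicate numbers do not pair the arrays: 5 of 18 same-number pairs had deviations correlated over 0.1 (from -0.56 to 0.61) and 3 of 12 arrays correlated best with their own number. With the replicate block 7602, 11396, 9510, 13268, 11957 and 7980 targets were called in the 6 contrasts, in the order of the thresholds above, and no count moved by over 1.5 times. For the interaction the 2-group fit and unequal-variance test were not run, and the table of the whole series was not run as it held the same values. Signal over background limits dim targets: 24350 of 37157 had a mean above the random-probe level.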

Other observations

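All lists of this part were formed by symbol pattern, and all tests and values here were chosen only after the data were seen.

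Rab GTPase genes, which direct vesicle traffic, were called lower as a list in cdc73 morphants, where 10 of 15 fell and none rose (median -0.88, camera adjusted p = 0.00121; adjusted p = 0.298 with an estimated correlation). After removal of the trend with probe reach and level 8 fell and 1 rose (median -0.56, camera adjusted p = 0.00296). In TIF1g morphants 4 fell (median -0.26, camera adjusted p = 0.00557; adjusted p = 0.263 with an estimated correlation), and 6 after removal of the trend (median -0.40, camera adjusted p = 0.0369). In double morphants 5 fell (median -0.23, camera adjusted p = 0.0370; adjusted p = 0.433 with an estimated correlation), a list call that was lost after removal of the trend (camera adjusted p = 0.117). The double morphants lay above the sum of both effects for 7 Rab genes and below it for none (median 0.48, camera adjusted p = 0.00604; adjusted p = 0.230 with an estimated correlation). The list's median reach was 1344 bases, and bright targets reaching over 1000 and up to 2000 bases had a median of 0.37 in the interaction. After removal of the trend 5 Rab genes lay above the sum (median 0.18, camera adjusted p = 0.0441).

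Of 13 mitochondrial ribosomal protein genes, which build the ribosomes of mitochondria, 3 fell and none rose in TIF1g morphants (median log2 -0.29, camera adjusted p = 0.00557; adjusted p = 0.263 with an estimated correlation). The list's median reach was 587 bases, and bright targets reaching over 500 and up to 1000 bases had a median of -0.16 in the same comparison. In double morphants 7 fell and none rose (median -0.38, camera adjusted p = 0.00463; adjusted p = 0.408 with an estimated correlation), and against cdc73 morphants 10 were lower and 1 higher in double morphants (median -0.54, camera adjusted p = 0.00163; adjusted p = 0.306 with an estimated correlation). None of these 3 list calls held after removal of the trend with probe reach and level (medians -0.11, -0.06 and -0.38; camera adjusted p = 0.277, 0.221 and 0.0978). In cdc73 morphants 2 rose and 2 fell (camera adjusted p = 0.510).

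Contractile protein genes were not called as a list in any of the 6 contrasts. In TIF1g morphants 6 of 22 rose and 3 fell (camera adjusted p = 0.239), from TIF1g to double morphants 2 rose and 8 fell (camera adjusted p = 0.204), and the interaction had 5 genes below the sum (camera adjusted p = 0.0542). Of 20 chaperone genes 11 fell and 3 rose in cdc73 morphants, not called as a list (camera adjusted p = 0.149), with 5 higher and 3 lower in TIF1g morphants (camera adjusted p = 0.639). Of 10 sterol synthesis and uptake genes 4 fell and 1 rose in cdc73 morphants (camera adjusted p = 0.526). Lens and odorant or taste receptor genes (45), solute carriers (67) and cytochrome P450 genes (24) were not called in TIF1g morphants (camera adjusted p = 0.884, 0.884 and 0.533) or double morphants (camera adjusted p = 0.205, 0.547 and 0.611).

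Across arrays, 50.1% of the variance between the 12 target profiles lay on a first component with the TIF1g arrays at 1 end (from -121 to -45.4) and the cdc73 arrays at the other (82.1 to 91.1). The wild-type arrays (-33.0 to 13.5) and the double-morphant arrays (-6.90 to 29.7) lay between them. This component also followed array background within the TIF1g, cdc73 and double-morphant groups, where arrays with brighter random probes lay lower on it. TIF1g arrays with a background of 632, 391 and 312 lay at -121, -84.2 and -45.4. The order differed in wild type. The component thus cannot be assigned to the knockdowns alone. The second component, 19.7%, set the double-morphant arrays (58.1 to 78.2) apart from all others (-34.0 to 0.44).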
